A study of Mus musculus with 6 samples.

How the data were processed

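RNA of the duodenum (the 2 cm nearest the stomach) had been prepared with a TruSeq RNA kit from total RNA with a RIN above 8 and sequenced on a HiSeq2000, per the labels. The submitters' notes name CASAVA 1.8.2, TopHat, Cufflinks, DESeq and the mm9 genome without stating options, strand or the role of each. For each library the authors deposited FPKM per gene (23699 gene models) and per isoform (30028), made with Cufflinks, and the isoform files also hold a coverage signal, per the file headers. A deposited table by the authors, made with DESeq per its name, gives mean normalized counts per group as a signal, their ratio as a fold change, its log2, a p-value and an adjusted p-value, but no count per library. The ratio of FPKM to coverage was constant in each library and gave its depth in fragments (21.0 to 26.3 M). Reads per gene were rebuilt from coverage with a fitted read length of 100.9 bases, and 93.0% of 17824 values of at most 20 reads lay within 0.1 of a whole read. At these depths genes of few FPKM and short transcripts rest on few fragments: 1 rebuilt read corresponded to 1 fragment, within 0.1, in 86.9% of 4221 such values of the Cufflinks intervals. Rows that share a gene name (712) were kept apart by locus.

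Samples were grouped by their titles into 3 control and 3 mutant libraries. Genes with an FPKM of at least 0.5 in at least 3 libraries (13596) were compared as log2(FPKM + 0.5) with limma 3.58.1 (lmFit, eBayes with trend and robust prior, statmod 1.5.0) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Isoforms (16213 kept) were compared in the same way. Of the tested genes, 56 carried the Cufflinks status LOWDATA and 26 FAIL in at least 1 library and were kept. Gene lists for 34 cell types and pathways were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives, and members were counted over all genes and adjusted over the list alone; 6 list members matched no gene model. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 served for the exact tests and summaries, matplotlib 3.10.9 for the plots, and minimap2 2.31-r1302 for a search of the mm9 genome for copies of transcripts (at least 95% identity over at least 50% of the transcript).

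Comparisons, lists, thresholds and the alternatives not named as added were fixed before the data were examined. Genes are named by a rule of that time: Nkx2-2, Neurog3, Tph1, Lmx1a and Ghrl; the 10 largest rises and falls past the threshold without overlap between groups, or, where fewer than 5 passed, the 5 of smallest p in that direction as values, leaving out predicted models and small RNAs; up to 4 members of each list past the threshold, or 2 of highest mean as values; and the expressed hormones. Members past the threshold over a list alone, genes called with the block only, Snora17, Ahcy, Xist, Reg3g, Slc6a4, Ins2 and the genes discussed in the closing section were added after their values were seen. Genes given as values have no call, and their movement between settings was judged against the SD of the replicates, a choice made after seeing the results; of 105 named genes, 34 such values changed sign in at least 1 setting.

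Both groups carry the numbers 1 to 3, and the labels do not say what a number marks. Deviations from the group means correlated within the same-numbered pairs at 0.26, 0.25 and 0.58, so the numbers were taken to pair the samples, although control 1 correlated at 0.30 with mutant 2 and control 2 at 0.19 with mutant 1. The pairing mainly sets both libraries numbered 3 apart. Deviations cancel out within each group, so the value of 0.58 by itself brings positive values among the other libraries. The match of 1 with 1 and of 2 with 2 is therefore not shown by these values. A block with that match swapped was not run, so all calls with the block rest on an assumed pairing. Calls that a fit with the replicate number as a block adds or loses are given beside those of the main fit.

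In data simulated on these libraries with 200 changed genes, the limma test recovered 58.0% of genes with a log2 change of 1 and 90.6% of those with 2, and 4.13% of calls were false. For isoforms these were 37.8%, 75.7% and 5.02%. These rates hold for 200 changed genes or isoforms. In the data 3 genes passed, and Gip (log2 change -2.90) and Tph1 (-2.82) did not, so a gene not called may still differ. A list shifted by 1 was called in 10 of 10 simulations and other lists in 0 of 330 tests, both with the preset and with an estimated correlation. In the data 0 lists passed with an estimated correlation. The simulated rates therefore do not show how often camera at the preset correlation calls a list falsely here. Alternatives were other pseudocounts (0.1 and 1), no filter, an FPKM minimum of 1, quantile, upper quartile and TPM scaling, library quality weights, no trend or robust prior, the replicate block, an adjusted p of 0.1 and leaving out each library. Chosen after seeing the data were limma-voom on rebuilt reads, a term for sex, leaving out both libraries numbered 3, leaving out LOWDATA genes and leaving out genes under 200 bases. Raw reads were not analysed here.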

Results

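Transcripts of the whole duodenum were measured by RNA sequencing in 3 control and 3 mutant samples from 6-week-old mice of mixed background. Controls were Nkx2.2flox/+. Mutants were Nkx2.2flox/flox;Villin-Cre/+, a genotype made to delete Nkx2-2, a homeodomain transcription factor of endocrine cells, in the intestinal epithelium. Mutant 3 also carried a Rosa26Tomato/+ reporter allele. The depth behind the deposited values was 26.3, 21.8 and 21.5 M fragments in controls 1 to 3 and 21.3, 23.8 and 21.0 M fragments in mutants 1 to 3. Of 23699 gene models, 13596 had an FPKM of at least 0.5 in at least 3 libraries and were tested. All changes are mutant minus control, levels are mean FPKM ± SD with n = 3 in each group, and log2 changes are given with their standard error. The p-values measure the spread between these samples, since the labels do not say in words that each sample is a separate animal.

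The first question was how far the targeted transcript itself differed. Nkx2-2 (chromosome 2, 147003282 to 147012138, mm9) lay at 1.13, 1.32 and 0.779 FPKM in controls 1 to 3 and at 1.10, 0.736 and 0.221 FPKM in mutants 1 to 3. Its log2 change was -0.47 ± 0.30, and an exact two-sided permutation test gave p = 0.2, where 3 samples against 3 cannot go below 0.1. The isoforms of the gene differed more than the gene total. The isoform of 2049 bases, which starts at 147008888, lay at 0.942, 1.07 and 0.464 FPKM in controls and at 0.0803, 7.37e-09 and 0.130 FPKM in mutants. The isoform of 1354 bases, which starts at 147003282, lay at 0.184, 0.250 and 0.315 FPKM in controls and at 1.02, 0.736 and 0.0912 FPKM in mutants. Both isoforms were too low to be tested, the labels do not say which exons are floxed, and whole duodenum also holds cells in which Villin-Cre is not active.

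The main comparison asked which transcripts differed between mutant and control duodenum, and the hormones of enteroendocrine cells, the scattered hormone-secreting cells of the gut epithelium, stood out. Ghrl (chromosome 6, 113666113 to 113669874), which encodes the appetite hormone ghrelin, rose from 70.6 ± 11.9 to 1108 ± 402 FPKM (log2 change 3.90 ± 0.30, limma adjusted p = 0.0276), and lay higher in all 3 mutants. Tac1 (chromosome 6, 7505071 to 7512973), the precursor of the neuropeptide substance P, fell from 11.0 ± 0.286 to 1.796 ± 0.740 FPKM (log2 change -2.38 ± 0.23, adjusted p = 0.0491), and lay lower in all 3 mutants. The other transcript past the threshold was Snora17, a small nucleolar RNA under 200 bases, which rested on 1 fragment in each control library and 0 in each mutant library. In all, 3 genes passed the adjusted threshold, 1 higher and 2 lower, and 467 genes passed an unadjusted p of 0.05, of which 245 were higher and 222 lower. Values of mutants and controls did not overlap in 1054 genes, 7.75% of those tested, where chance gives 10%. Without transcripts under 200 bases, a setting chosen after seeing the data, limma called 0 genes (466 at an unadjusted p under 0.05). The adjusted p was then 0.0522 for Ghrl and 0.0684 for Tac1. Limma-voom on rebuilt reads, also chosen after seeing the data, tested 13482 genes and called 0, with 459 at an unadjusted p under 0.05. With the replicate number as a block, 22 genes passed, 9 higher and 13 lower, the adjusted p was 0.000174 for Ghrl and 0.000673 for Tac1, and 68 genes passed without mutant 3 and 8 without mutant 1. Of those 8, 4 are Y-linked (Kdm5d, Eif2s3y, Uty and Ddx3y), since the 2 mutants left were the 2 that expressed Xist. The call of Ghrl was lost without control 1 (0.130), control 2 (0.202), control 3 (0.0825) or mutant 2 (0.115), and that of Tac1 without control 1 (0.310), control 2 (0.317), control 3 (0.0964) or mutant 1 (0.0968).

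Among 13 tested enteroendocrine hormones, 1 rose and 8 fell when adjusted over the list alone, and 1 rose and 1 fell over all genes tested. The counts over the list alone were again 1 and 8 without any 1 of the 6 libraries. Gip, the glucose-dependent insulinotropic polypeptide of K cells, fell from 138 ± 29.4 to 18.8 ± 7.67 FPKM with the test adjusted over the list alone (log2 change -2.90 ± 0.31). Sst, which encodes somatostatin, fell from 70.5 ± 14.0 to 23.0 ± 8.05 FPKM. Pyy, the peptide hormone of L cells, fell from 15.3 ± 4.46 to 2.26 ± 1.76 FPKM. Sct, the duodenal hormone secretin, fell from 136 ± 32.4 to 68.6 ± 17.3 FPKM, and Cck, cholecystokinin of I cells, fell from 75.9 ± 5.38 to 49.7 ± 10.9 FPKM. Ucn3 (1.66 ± 0.328 to 0.157 ± 0.0888 FPKM) and Nts, which encodes neurotensin (1.02 ± 0.270 to 0.0470 ± 0.00322 FPKM), also fell over the list alone. Adjusted over all genes with limma, these 7 had adjusted p-values of 0.114 for Gip, 0.326 for Sst, 0.751 for Pyy, 0.999 for Sct and Cck, 0.072 for Ucn3 and 0.114 for Nts; with the block, Sct (0.00219), Ucn3 (0.00526) and Nts (0.0183) passed. With the block 2 rose and 8 fell over the list alone, as Nmb passed too (0.0403). The hormones that did not pass in the main fit were Gcg, the proglucagon gene (5.13 ± 0.818 to 5.72 ± 2.68 FPKM), Gast (2.37 ± 3.48 to 0.443 ± 0.302 FPKM), Iapp (1.87 ± 0.431 to 2.48 ± 1.75 FPKM) and Nmb (1.64 ± 0.996 to 2.43 ± 1.20 FPKM). As a set the hormones lay lower (median log2 change -0.99, camera adjusted p = 2.15e-09), at list medians of -0.85, -1.33 and -1.44 in mutants 1 to 3 and -0.25 to 0.11 in controls. The set's adjusted p was 0.0897 with an estimated correlation and 0.0134 by fry, and with the block 0.473 and 0.142, so that the fry call was lost. Transcripts of the exocrine pancreas also had a lower median in the mutants (log2 change -1.36), although mutant 1 (-0.42) lay next to control 3 (-0.39). With an estimated correlation that set did not pass (camera adjusted p = 0.438).

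**Figure D1:**
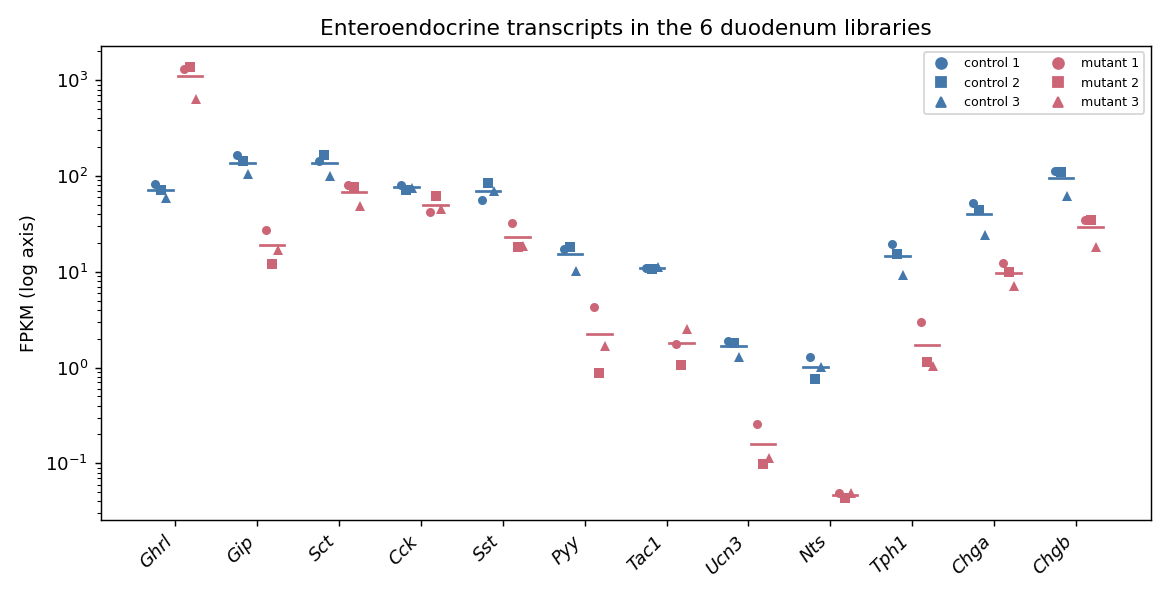
FPKM on a log axis of 12 enteroendocrine transcripts in each of the 3 control and 3 mutant libraries. Marker shape gives the replicate number and the line the group mean. Ghrl lay between 58.6 and 82.4 FPKM in controls and between 644 and 1360 FPKM in mutants, while Gip lay between 106 and 164 FPKM in controls and between 12.2 and 27.2 FPKM in mutants.

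Genes of enterochromaffin cells, which make serotonin, were lower in the mutants. Tph1 (chromosome 7, 53902501 to 53927907), the rate-limiting enzyme of peripheral serotonin synthesis, lay at 14.7 ± 5.18 FPKM in controls and 1.72 ± 1.10 FPKM in mutants (log2 change -2.82 ± 0.40). Of 16 tested members 8 fell and 0 rose when adjusted over the list alone, namely Tph1, Tac1, Ucn3, Trpa1, Chga, Amigo2, Chgb and Fev, and 1 of them, Tac1, over all genes. Trpa1, an irritant-sensing ion channel, fell over the list alone from 2.01 ± 0.849 to 0.306 ± 0.0690 FPKM. Chga, a granule protein, fell from 40.1 ± 14.6 to 9.79 ± 2.68 FPKM, and Chgb from 94.9 ± 29.2 to 29.1 ± 9.40 FPKM. Slc6a4, the serotonin transporter, had a log2 change of 0.47 and did not pass. With the block it rose over the list alone (0.0441), as did Maob (0.0374), and without both libraries numbered 3 it passed over all genes (0.0401). Over all genes the adjusted p was 0.305 for Tph1, 0.512 for Chga and 0.866 for Chgb, and with the block 0.000129, 0.000106 and 4.56e-05. The set test gave a median log2 change of -0.81 and a camera adjusted p of 9.44e-12 (adjusted p = 0.305 with an estimated correlation), at list medians of -0.39, -0.60 and -1.23 in mutants 1 to 3 and -0.27 to 0.20 in controls. Lmx1a, a transcription factor of enterochromaffin cells, was under the filter, at 0.828, 0.704 and 0.268 FPKM in controls and 0.0901, 0 and 0.0763 FPKM in mutants.

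Genes of ghrelin-producing cells were higher. Over that list of 6 tested members, 2 rose and 0 fell when adjusted over the list alone, Ghrl and Mboat4, the enzyme that acylates ghrelin, which rose from 0.147 ± 0.0680 to 1.56 ± 0.892 FPKM (adjusted p = 0.999 over all genes). The list's median log2 change was 0.60 and its camera adjusted p 8.14e-06 (adjusted p = 0.305 with an estimated correlation), and with the block Acsl1 also rose over the list alone (0.0268). Medians of the 6 members were 0.84, 1.04 and 0.21 in mutants 1 to 3 and -0.07 to 0.04 in controls. The set of 16 enteroendocrine transcription factors did not pass (adjusted p = 0.103) and passed lower without control 3 (0.0186) or mutant 1 (0.0132). With the block Neurod1 (0.0465) and Fev (0.0197) fell and Isl1 rose (0.0465) over that list alone. Neurog3, the proendocrine factor, lay at 2.75 ± 0.200 FPKM in controls and 2.04 ± 0.246 FPKM in mutants and did not pass in limma. Exact two-sided permutation tests of Neurog3, Tph1, Lmx1a and Ghrl each gave p = 0.1, the smallest that 3 against 3 allows. Of 23 granule and secretion genes, 3 fell over the list alone, namely Chga, Chgb and Scg2 (9.93 ± 0.0338 to 7.27 ± 0.519 FPKM), while Cpe, a prohormone-processing carboxypeptidase, lay at 38.6 ± 4.87 FPKM in controls and 60.7 ± 15.03 FPKM in mutants. That set lay lower (median -0.10, camera adjusted p = 0.00193, adjusted p = 0.512 with an estimated correlation), and its adjusted p was 0.713 without mutant 3, while 0 members passed without control 1, control 2 or mutant 2. The list medians of mutants 1 and 2 (-0.05 and -0.07) lay within the controls (-0.08 to 0.08), and that of mutant 3 at -0.27. Of 6 nutrient receptors 1 fell over the list alone, Trpa1, and the set did not pass (adjusted p = 0.549).

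The genes of smallest p outside those lists included Afp, which encodes alpha-fetoprotein, at 20.4 ± 8.53 FPKM in controls and 1.14 ± 0.699 FPKM in mutants (log2 change -3.66 ± 0.45, adjusted p = 0.220). Higher in all 3 mutants but short of the threshold were Plb1, an intestinal phospholipase (0.126 ± 0.0663 to 1.66 ± 0.661 FPKM), the potassium channel gene Kcnk16 (0.513 ± 0.299 to 3.16 ± 1.10 FPKM), Tbc1d23 (11.2 ± 0.917 to 19.2 ± 0.577 FPKM) and Asb11 (8.46 ± 1.33 to 15.8 ± 0.826 FPKM), with limma adjusted p-values between 0.166 and 0.289. These 4 passed with the replicate block (adjusted p 0.0183, 0.00616, 0.0355 and 0.0493). The block also called the neuropeptide gene Nmu (0.849 ± 0.488 to 5.21 ± 2.46 FPKM, blocked adjusted p = 0.000673), the lectin gene Mbl2 (1.65 ± 1.48 to 10.5 ± 4.96 FPKM, 0.000225), the clock output gene Dbp (27.9 ± 9.68 to 52.8 ± 7.93 FPKM, 0.0110) and Ace, a brush border peptidase (112 ± 32.6 to 208 ± 85.7 FPKM, 0.0259), all higher in mutants. Lower with the block were the neuropeptide gene Npy (12.2 ± 3.99 to 4.69 ± 2.06 FPKM, 0.00645), Vip (21.7 ± 4.03 to 11.6 ± 0.648 FPKM, 0.0440), Serinc3 (329 ± 37.0 to 202 ± 5.16 FPKM, 0.0472), the carboxylesterase gene Ces2a (133 ± 120 to 80.9 ± 83.2 FPKM, 0.0142) and Snora28, a small nucleolar RNA that rested on between 1 and 6 fragments per library. In the unblocked test these 9 genes had adjusted p-values between 0.368 and 0.999. All but Dbp and Vip were named after their values were seen.

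Markers of tuft cells, the chemosensory cells of the gut epithelium, were higher in mutants 1 and 2. Alox5ap, a leukotriene synthesis protein, lay at 9.48 ± 2.32 FPKM in controls and 31.7 ± 19.3 FPKM in mutants. All 12 tested markers had a higher mean log2 level in mutants, 0 passed when adjusted over the list alone (10 without mutant 3, and Ltc4s with the block), and the median of the list relative to the control mean was 1.85, 2.10 and -0.10 in mutants 1 to 3. As a set they lay higher (median log2 change 1.28, camera adjusted p = 9.44e-10; adjusted p = 0.438 with an estimated correlation). Among 15 goblet cell markers 1 rose over the list alone, Retnlb, a secreted goblet cell protein with antibacterial activity, from 8.21 ± 11.0 to 630 ± 157 FPKM (log2 change 6.99 ± 1.00, adjusted p = 0.512 over all genes). Without control 3, where Retnlb lay at 20.9 FPKM, its log2 change was 8.06 and its adjusted p 0.000243, while it did not pass over its list without control 1, mutant 1 or mutant 2, or with the block (0.0742), where Clca3 rose and Fcgbp, Zg16 and Klk1 fell (0.0389 each). The goblet set did not pass (adjusted p = 0.618), with Tff3 at 3033 ± 193 FPKM in controls and 2887 ± 419 FPKM in mutants. Mcpt1, a protease of mucosal mast cells, rose over its list of 15 myeloid and mast cell markers alone, from 5.01 ± 1.29 to 16.5 ± 7.23 FPKM (adjusted p = 0.767 over all genes), and that set did not pass (adjusted p = 0.144). With the block Mcpt2 rose as well (0.00602). Mcpt1 did not pass over its list without control 1 or control 2, and the set passed without mutant 2 (0.0162).

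Interferon response genes lay higher as a set, with 2 of 17 that rose over the list alone and 0 that fell. These were Oas2, an antiviral enzyme (0.748 ± 0.336 to 3.90 ± 2.25 FPKM), and Ifi44 (1.28 ± 0.648 to 3.50 ± 0.742 FPKM). Irf7, the interferon regulatory factor, lay at 55.0 ± 13.4 FPKM in controls and 113 ± 52.3 FPKM in mutants. The set's median log2 change was 0.76 (camera adjusted p = 5.73e-10; adjusted p = 0.440 with an estimated correlation). Over the list alone 0 rose without control 1 or control 2, 1 without mutant 2 or mutant 3, 4 without control 3 and 0 with the block. The list median was 0.46, 1.495 and 0.71 in mutants 1 to 3 relative to the control mean, and 0.57 in control 3. Digestive enzymes of the exocrine pancreas lay lower in 18 of 19 members, with Ctrb1, a chymotrypsinogen, at 4307 ± 498 FPKM in controls and 1614 ± 848 FPKM in mutants. None of the 19 passed in limma over the list alone and 8 fell with the block, 14 without mutant 1 and 6 without mutant 3 (set median -1.36, camera adjusted p = 6.85e-12; adjusted p = 0.438 with an estimated correlation). Per library this list lay at a median of -0.42, -0.999 and -2.62 in mutants 1 to 3 relative to the control mean, so that mutant 1 lay next to control 3 (-0.39). Markers of Brunner glands and stomach lay lower as a set (median -2.20, camera adjusted p = 0.000109; adjusted p = 0.512 with an estimated correlation), with the mucosal peptide gene Tff2 at 3590 ± 2347 FPKM in controls and 1532 ± 1862 FPKM in mutants. That call was lost without mutant 3 (adjusted p = 0.273), and mutant 1 (list median 0.10) lay within the controls (-1.05 to 1.17).

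Proliferation genes lay lower in all 20 members by small amounts (median log2 change -0.27, camera adjusted p = 2.39e-06; adjusted p = 0.512 with an estimated correlation), with Birc5, a mitotic protein, at 52.8 ± 7.88 FPKM in controls and 47.6 ± 16.1 FPKM in mutants. The list median was -0.44 and -0.48 in mutants 1 and 2 relative to the control mean, but 0.10 in mutant 3, within the controls (-0.07 to 0.15). Cholesterol synthesis genes lay lower (median -0.32, 1.76e-05; adjusted p = 0.526 with an estimated correlation), with Insig1, a regulator of sterol synthesis, at 82.8 ± 8.84 and 68.0 ± 27.6 FPKM, and that call was lost without mutant 3 (adjusted p = 0.458), where the list median was -0.61, against -0.14 and -0.17 in mutants 1 and 2, within the controls (-0.17 to 0.20). Enteric neuron and glia markers lay lower in all 11 members (median -0.26, 3.21e-05; adjusted p = 0.438 with an estimated correlation), and 1 of them fell over the list alone, Vip, which encodes the neuropeptide vasoactive intestinal peptide. In this list the median was -0.16 and -0.42 in mutants 1 and 2 and -0.12 in mutant 3, within the controls (-0.13 to 0.12). Enterocyte genes lay higher in 23 of 26 members (median 0.17, 3.72e-04; adjusted p = 0.597 with an estimated correlation), with Apoa1, an apolipoprotein, at 7676 ± 3477 and 8562 ± 3129 FPKM, and the call was lost without control 3 (adjusted p = 0.378) and without mutant 2 (0.399). Medians of this list were 0.22, 0.55 and -0.11 in mutants 1 to 3 and between -0.25 and 0.20 in controls. Circadian clock genes lay higher in 12 of 16 members (median 0.27, 0.00129; adjusted p = 0.305 with an estimated correlation), and the call was lost without control 3 (0.106). The list median of mutant 3 (0.16) lay within the controls (-0.25 to 0.19). None of these lists except that of neurons and glia had a member past the threshold over the list alone in the main fit. With the block 3 enterocyte genes (Slc5a1, Dpp4 and Ace) and 4 clock genes (Per1, Nr1d2, Dbp and Hlf) rose.

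Of the 34 lists, 14 passed with the preset correlation, 5 higher and 9 lower, and 16 with the block, among them the same 14. With an estimated correlation 0 passed, with or without the block, and by fry 1 passed, the hormones, 0 with the block, and 7 passed in either direction. Over the list alone the block also called Acadl (higher, 0.0191), Cybrd1 (higher, 0.0341), Isx (lower, 0.0104) and Ugt1a1 (lower, 0.00760). The 20 lists that did not pass had adjusted p-values between 0.0934 and 0.980 and medians between -0.74 and 0.17. Beside those named above they covered Paneth cells (Defa24 at 7568 ± 1506 and 9511 ± 2329 FPKM in controls and mutants), stem cells (Olfm4 at 240 ± 73.2 and 226 ± 19.7 FPKM), lipid uptake, fatty acid oxidation (Acaa2 at 347 ± 66.2 and 350 ± 50.3 FPKM), iron and vitamin genes, bile acid genes, T cells (Gzma at 149 ± 28.8 and 172 ± 34.0 FPKM), B cells, smooth muscle (Acta2 at 168 ± 65.7 and 154 ± 36.3 FPKM), fibroblasts and vessels, pancreatic islets (Pdx1 at 89.8 ± 3.42 and 81.5 ± 4.26 FPKM), adipocytes, blood cells, and immediate early genes (Fos at 99.7 ± 6.85 and 116 ± 7.34 FPKM). Genes of antigen presentation by MHC class II lay at a median of -0.74 (adjusted p = 0.0934), with Cd74 at 951 ± 505 and 557 ± 288 FPKM, and passed with the block (2.51e-06, with 6 members that fell over the list alone and 1 that rose, but 0.492 with an estimated correlation), without control 2 (0.000148) and without mutant 3 (0.0231). Antimicrobial and regenerating genes lay at a median of -0.59 (adjusted p = 0.247) and also passed with the block (0.0130, but 0.667 with an estimated correlation), without control 1 (0.01002) and without mutant 3 (0.0188). The T cell list passed higher without control 1 (0.00959), the islet list lower without mutant 1 (0.00979), the iron and vitamin list without mutant 2 (0.0206), and the lipid list higher without control 1 (0.0235) or mutant 3 (0.0188). The smooth muscle list passed lower without control 2 (0.00379) and higher without control 3 (0.00649). In 7 lists, none of which passed, the median, the mean and the set test differed in sign. They were the lists of Paneth cells, fatty acid oxidation, iron and vitamins, bile acids, B cells, blood cells and immediate early genes.

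**Figure D2:**
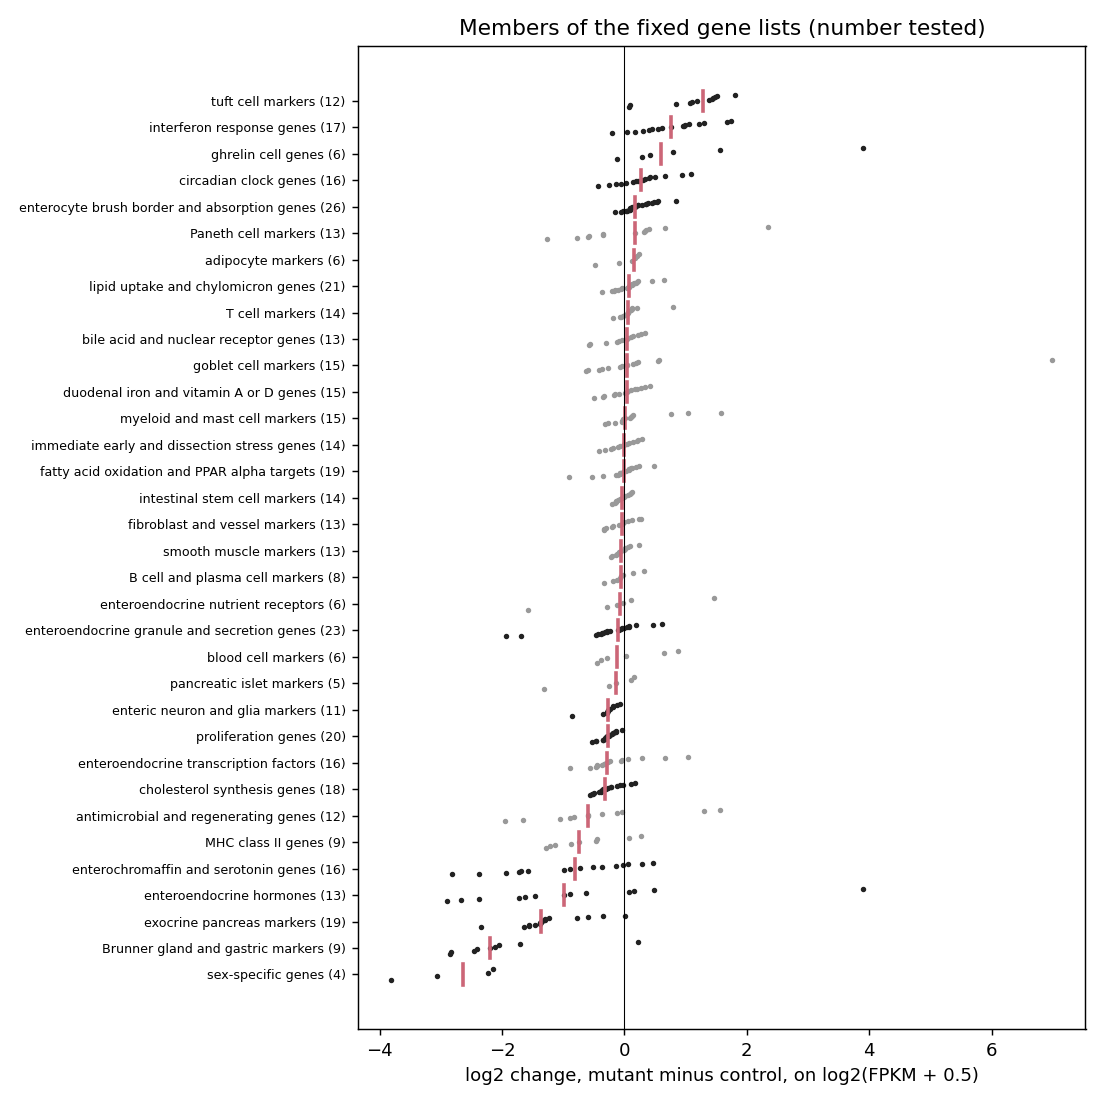
Log2 change, mutant minus control, of each tested member of the 34 gene lists, with the list median as a red bar. Black points mark the 14 lists with a camera adjusted p under 0.05 at the preset correlation and grey points the other 20. The medians of the hormones (-0.99), the exocrine pancreas (-1.36) and the tuft cells (1.28) lie away from 0.

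The libraries also differed within groups. The antibacterial lectin gene Reg3b lay at 42934 FPKM in control 3 and 47743 FPKM in mutant 3, against 1467 and 5823 FPKM in controls 1 and 2 and 651 and 207 FPKM in mutants 1 and 2. The first principal component held 43.7% of the variance and placed control 3 (33.2) and mutant 3 (32.3) apart from the other 4 libraries (-29.3 to -6.45). The Y-linked gene Ddx3y was expressed in controls 1 to 3 and mutant 1 (11.4 to 13.8 FPKM) and Xist, the transcript of the inactive X chromosome, in mutants 2 and 3 (19.7 and 22.5 FPKM, and at most 0.0894 FPKM elsewhere). The list of sex-specific genes lay lower (median -2.64, camera adjusted p = 0.000109; adjusted p = 0.438 with an estimated correlation), and its adjusted p was 0.0702 without mutant 3. Its median was 0.03 in mutant 1, within the controls, and -3.95 and -4.01 in mutants 2 and 3. Without both libraries numbered 3, a setting chosen after seeing the data, 200 genes passed, 145 higher and 55 lower in mutants, among them 10 of 12 tuft cell markers and 14 genes of the enteroendocrine lists. This setting leaves out mutant 3, the mutant without higher tuft markers, so the tuft count is no separate evidence of a genotype effect.

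**Figure D3:**
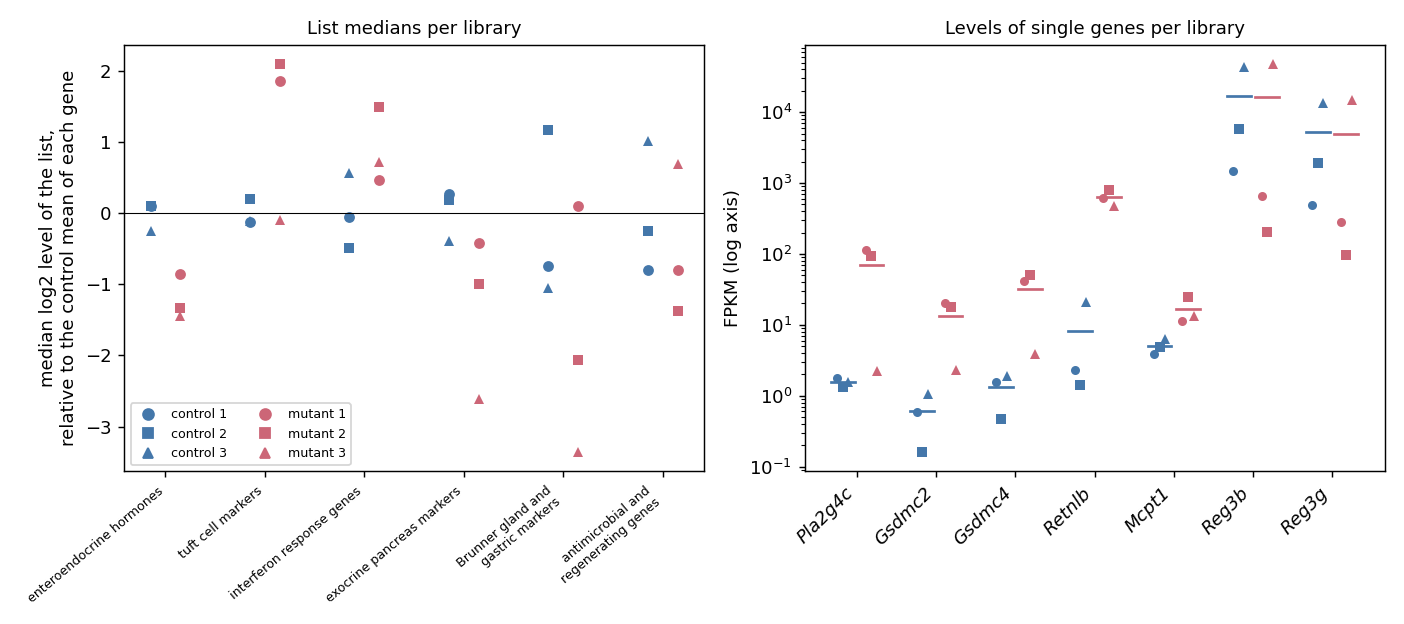
Left, median log2 level of 6 gene lists in each library relative to the control mean. Right, FPKM on a log axis of 7 genes in each library, with lines at the group means and marker shape for the replicate number. Mutants 1 and 2 lie high in the tuft list (1.85 and 2.10) and mutant 3 at -0.10, while Reg3b and Reg3g are high in control 3 and mutant 3.

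The deposited table of the same comparison, made by the authors with DESeq, listed 26 of 23284 genes at an adjusted p under 0.05, 9 higher and 17 lower in mutants. Xist was among those higher (15.5 to 5448 normalized counts, DESeq adjusted p = 0.0423). It was expressed in mutants 2 and 3 only, so this entry goes with the sex of the samples. Xist was not tested here, nor were Irs4 of the ghrelin cell list (higher, DESeq adjusted p = 0.000217) and Trpc7 (lower, 0.0423). In normalized counts by the authors, Ghrl rose from 533 to 8729 (16.4-fold, DESeq adjusted p = 6.22e-05) and Tac1 fell from 217 to 36.5. Gip fell from 1409 to 190 and Tph1 from 519 to 60.7 (DESeq adjusted p = 0.00194). Retnlb rose from 88.2 to 7152 (81.1-fold, DESeq adjusted p = 5.43e-20). Ahcy, which encodes adenosylhomocysteinase, had the smallest p in that table, from 401 to 63.5 normalized counts, whereas its FPKM lay at 53.1 ± 1.98 in controls and 35.8 ± 3.27 in mutants (log2 change -0.57 ± 0.10, limma adjusted p = 0.490), and the genome holds near-identical copies of its transcript. Snora17 lay at 4.18 and 4.13 normalized counts in that table. Genes short of the limma threshold here that passed there by DESeq adjusted p included Gip (3.31e-10), Ucn3 (4.15e-07), Sst (1.79e-06) and Plb1 (6.46e-06). Nts (0.000212), Afp (0.000212) and Pyy (0.00117) passed there too. By the same DESeq adjusted p, Chgb (0.105), Chga (0.133), Sct (0.635) and Cck did not pass. Of the 26 genes, 23 were also tested here, and 23 had the same sign and an unadjusted p under 0.05. They included 2 of the 3 genes called here and 9 of the 22 called with the block. Independent lists would share 0.00515 and 0.0377 genes, but both analyses test the same libraries, so these values are no measure of agreement. Of 67 genes in the 5 enteroendocrine lists, 11 were among these 23 genes (Fisher's exact test, two-sided, p = 2.64e-20). That test takes genes as independent, whereas genes of the same cells can move together and all calls come from the same libraries. Its p-value therefore does not measure the spread between samples.

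At the level of single isoforms, Snora17 was the 1 called of 16213 tested, with 614 at an unadjusted p under 0.05 and 3 called with the block. Within 10 Mb of Nkx2-2 on chromosome 2, 0 of 136 tested genes were called by limma. At an unadjusted p of 0.05 this region held 6 genes (4.41%) against 3.42% elsewhere (Fisher's exact test, two-sided, p = 0.474). With the block the share turned, at 5.15% against 6.78% elsewhere (Fisher's exact test, two-sided, p = 0.605).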

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

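The settings with limma-voom, a term for sex, no libraries numbered 3, no LOWDATA genes and no genes under 200 bases were chosen after the data were seen. Ghrl stayed higher (log2 change 3.71 to 4.25) and Tac1 lower (-2.70 to -2.13) in all 21 settings run, with adjusted p-values of 1.57e-07 to 0.202 and 0.000221 to 0.866, past the threshold in 11 and 10 settings. Gip, Sst, Pyy, Sct, Cck, Ucn3, Nts, Tph1, Chga and Chgb stayed lower in each setting that gave them a value. Where no cause is named, the cause was not tested. Without genes under 200 bases, 0 genes were called, 0 higher and 0 lower (Ghrl 0.0522), since 1 of the 3 smallest p-values, that of Snora17, left the adjustment. Voom on rebuilt reads called 0, 0 higher and 0 lower (smallest adjusted p 0.0685). Reads were rebuilt only for transcripts over 400 bases, so this setting also left out Snora17 and tested 13482 genes. No filter called 1, 0 higher and 1 lower, with 18816 genes tested, and upper quartile scaling called 1, 0 higher and 1 lower. A pseudocount of 0.1 left 1 lower, no trend and no robust prior 1 lower, and TPM and the sex term 0 higher. Quality weights called 19, 10 higher and 9 lower, and the replicate block 22, 9 higher and 13 lower. Without both libraries numbered 3 there were 200, 145 higher and 55 lower, and the authors' table held 26. Leaving out each library gave 2 to 68 genes (0 to 56 higher, 1 to 12 lower), with 68 without mutant 3 and 8, of which 4 Y-linked, without mutant 1, and 1 to 20 isoforms; isoforms numbered 4 without a filter and 3 with the block. Near Nkx2-2, the whole of chromosome 2 held 1 called gene, and at an unadjusted p of 0.05 there were 6 genes, 7 with the block, a share that turned to below that elsewhere, and 14 within 20 Mb. The change of Nkx2-2 was 0.041 with the sex term, which compares mutant 1 alone with the controls of its sex.

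With an estimated correlation 0 lists passed (hormones 0.0897, enterochromaffin 0.305, ghrelin cells 0.305), and with fry 1 passed (enterochromaffin 0.143, ghrelin cells 0.129). The self-test called a shifted list under both correlations, unlike the real lists, so it does not decide which correlation applies. At the preset correlation the block added the calls of MHC class II and the antimicrobial list and changed no other; by fry it removed the 1 call, that of the hormones (0.142), and with an estimated correlation 0 lists passed with it (hormones 0.473). Granule genes (0.713), Brunner glands (0.273), cholesterol synthesis (0.458) and sex-specific genes (0.0702) lost it without mutant 3, enterocytes without control 3 (0.378) and mutant 2 (0.399), and clock genes without control 3 (0.106). The same granule, Brunner gland, cholesterol and sex-specific lists also lost it with quality weights (0.221, 0.348, 0.326 and 0.543), with the sex term (0.446, 0.736, 0.451 and 0.364) and without both libraries numbered 3 (0.166, 0.119, 0.238 and 0.105), and sex-specific genes without a filter (0.0895). MHC class II gained a call with weights (0.0147), with the sex term (0.0456) and without both libraries numbered 3 (0.0186), and T cells with the sex term (0.00830).

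Directions reversed at these adjusted p-values. No filter: bile acids 0.999. FPKM of 1: B cells 0.940, blood 0.912. TPM: Paneth 0.936, iron 0.975, blood 0.977. Weights: Paneth 0.426, iron 0.728, B cells 0.938, islets 0.938, immediate early 0.520, and Gcg at a log2 change of -0.30. Block: Paneth 0.657, iron 0.812, bile acids 0.949, B cells 0.797. Voom: Paneth 0.857, blood 0.896. Sex term: Paneth 0.135, stem cells 0.952, iron 0.629, B cells 0.736, islets 0.364, immediate early 0.102, sex-specific 0.364, Gcg -0.45, Ces2a 0.83. Without libraries 3: Paneth 0.975, iron 0.455, B cells 0.823, smooth muscle 0.305, blood 0.535, Iapp -0.25. Fry: bile acids 0.993, B cells 0.993. Leaving out each library gave log2 changes of -0.25 to 0.33 for Gcg, -1.57 to 0.12 for Gast and -0.28 to 0.63 for Iapp. It gave adjusted p-values of 0.253 to 0.938 for Paneth cells, 0.393 to 0.730 for stem cells, 0.0188 to 0.818 for lipid uptake, 0.0688 to 0.938 for fatty acid oxidation, 0.0206 to 0.938 for iron, 0.0708 to 0.863 for bile acids, 0.01002 to 0.715 for antimicrobial genes, 0.231 to 0.831 for B cells, 0.00379 to 0.730 for smooth muscle, 0.313 to 0.730 for fibroblasts, 0.0825 to 0.938 for adipocytes, 0.167 to 0.832 for blood and 0.122 to 0.938 for immediate early genes. Of the comparisons of lists between settings, 653 kept direction and call, 64 reversed, 19 gained and 46 lost the call; of those of named genes, 2072 kept both, 35 moved by more than 1 SD, 8 reversed, 60 gained and 21 lost the call. The depth of 21.0 to 26.3 M fragments limits genes under about 1 FPKM and transcripts under 200 bases.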

Other observations

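Every test in this part was chosen after the results were seen, except the number of splits of the samples and the window of 10 Mb near Nkx2-2, which were set before the data were examined, although what each would show was written down afterwards. Several single genes, picked for their values and tested as no group, differed between the mutants. Pla2g4c, a phospholipase, lay at 1.78, 1.34 and 1.54 FPKM in controls 1 to 3 and at 114, 94.6 and 2.21 FPKM in mutants 1 to 3. Gsdmc2 and Gsdmc4, of the gasdermin C family, lay at 20.2 and 41.8 FPKM in mutant 1, at 18.0 and 50.2 FPKM in mutant 2 and at 2.32 and 3.92 FPKM in mutant 3, against at most 1.92 FPKM in controls; members of the family are near-identical, so reads may be divided between them. Ang4, an antimicrobial ribonuclease, lay at 2656, 1720 and 379 FPKM in mutants 1 to 3 and between 199 and 285 FPKM in controls. Retnlb lay at 619, 792 and 478 FPKM, and so was high in mutant 3 as well. None of these genes passed limma over all genes with all 6 libraries. Retnlb did pass in the comparison by the authors (DESeq adjusted p = 5.43e-20).

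The 3 genes called by limma were compared with the other ways to split the 6 libraries into 3 and 3. Of 10 splits, 1, the real one, called as many as 3 genes, the highest other called 2, and 10 splits are too few for a share under 0.05. Among the 4 splits that part all 3 numbered pairs, the highest other called 0, and these others had at most 388 genes at an unadjusted p under 0.05 against 467. The other splits leave a pair together: the one that sets control 1 with mutants 1 and 2 called 1 gene but had 2875 at an unadjusted p under 0.05, which points to the structure that separates both libraries numbered 3. Among splits of the 4 libraries left without number 3, the real one called 200 genes and the others 4 and 2. These are fewer than the 10 splits above, so they cannot give a share under 0.05 either. The real one also parts mutants 1 and 2, high in tuft markers, from the controls. Its count thus cannot tell genotype from whatever raised the tuft markers.

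Lower hormone transcripts together with higher Ghrl may reflect a shift among enteroendocrine cell types in the mutants, a hypothesis found on these data and not itself tested. Sex cannot be separated from genotype by a test here, since mutant 1 alone shared the sex of the controls. Its hormone list median was -0.85, against -0.25 to 0.11 in controls, and its Ghrl lay at 1320 FPKM, against 58.6 to 82.4 FPKM. The pattern was thus present in that library, but 1 library cannot decide. A loss of enteroendocrine cells of every kind also stays open, since the log2 change of Ghrl, 3.90, is part of the pattern itself and transcript per cell was not measured. Islet tissue in the control samples was argued against as the source of Sst, since the highest Ins2 level in a control was 15.1 FPKM, under the fall of 47.5 FPKM in Sst, and islets hold far more insulin than somatostatin transcript. The pancreatic or glandular tissue that differed between the samples stays open too.

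The tuft cell markers were high in mutants 1 and 2 but not in mutant 3, with 11, 11 and 1 of 12 markers above all 3 controls. A genotype effect alone cannot be told apart from a difference of 1 animal, as mutant 3 had 1 marker above the controls and also carried the reporter allele. Nor can an effect of the high Reg3b state of both libraries numbered 3, since control 3, the 1 control in it, lay at -0.11 in the tuft list relative to the control mean, within the other 2 controls. An exposure or litter that differed between the animals was not tested and stays open.

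Ahcy is the gene of smallest p in the authors' table but not in FPKM. Its counted reads in that table are 0.0991 of the reads rebuilt here, 0.140 in controls and 0.0347 in mutants, against a median of 1.00 over 11169 genes, and only 1.09% of genes had a lower ratio. The genome holds copies on chromosome 16 (99.7% identity) and chromosome 1 (98.7%), over 81.9% of the transcript, so a count that leaves out reads shared with copies is a candidate explanation for the low counts. Ahcy was the 1 gene with such a copy among the 25 of the authors' genes searched. It lies within 10 Mb of Nkx2-2, and a strain difference linked to the targeted allele stays open for the difference between groups, since the test of genes in that window decides nothing (Fisher's exact p = 0.474).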
